A study of Homo sapiens with 13 samples.

How the data were processed

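RNA from human non-small cell lung carcinoma cells was measured on 13 Affymetrix oligonucleotide arrays. The arrays held 2 of control cells without luciferase, 2 of control cells with luciferase and 3 each of the bone-metastatic lines M1, M4 and M5. The deposited values are log2 signals of 22277 probe sets made by the authors with RMA, per the submitters' processing notes. The software version and other steps of the authors' processing are not given in the sources used here. Only this table of processed values was analysed here, and the scanned images were not used here.

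The 62 Affymetrix control probe sets were left out of the gene tests. Of the others, 19064 name 1 gene, 1043 name several and 2108 list none, and the probe sets with several genes or none were tested apart. The probe set with the highest mean over all arrays stood for its gene, which gave 11963 genes. Of their gene identifiers, 11954 were found in the RefSeq table of assembly GRCh38.p14, which gave each gene's chromosome, and 11931 genes lay on chromosomes 1 to 22 and X. Symbols were used as the platform table gives them, and 0 needed an update. No gene was left out for a low signal.

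Differences were tested with limma (3.58.1, in R 4.3.3), which fitted the 5 group means over all 13 arrays with lmFit and eBayes. Control was the mean of the 2 kinds of control, and the mean of the lines weighted M1, M4 and M5 equally. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Errors beside log2 differences are limma's moderated standard errors, and those beside signals are SDs. Folds are 2 to the power of the log2 difference.

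The tests, the comparisons, the rule for naming genes and 30 gene lists were fixed before the data were examined. The lists cover epithelial identity and junctions, mesenchymal and EMT genes, extracellular proteases, osteolysis and bone metastasis factors, integrins, basement membrane and matrix glycoproteins, axon guidance, the TGF-beta response, Wnt, Notch, interferon-stimulated genes, MHC and antigen presentation, NF-kappaB targets, hypoxia, glycolysis, cholesterol and lipid synthesis, NRF2 targets, lung lineage, the cell cycle, p53 targets, EGFR and MAPK feedback, adhesion molecules, the unfolded protein response, immediate early genes and markers of fibroblasts, osteoblasts, osteoclasts, haematopoietic and endothelial cells. The last list holds the 4 genes that the published study singled out. Lists with at least 5 measured members were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Members were also counted after adjustment over the list alone. The chromosomes were tested with camera in the same way after the share of chromosome 3 had been seen. Medians were taken over windows of 31 neighbouring genes along it, using only genes above the median signal. The median shifts of single arrays also used only such genes.

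By the naming rule, genes of the mean of the lines had to be called there and in each line, with all metastatic arrays beyond all control arrays. For each line, genes called against control and against both other lines in the same direction were eligible, the 5 largest rises and the 5 largest falls whose higher mean lay above the median of all genes. For luciferase the 3 largest rises and falls were eligible. From each list 2 to 4 called members with the largest change were named, and all genes the study singled out. The rule was also applied to the fit with array batches. Genes named outside it are described as chosen after their values were seen.

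Array batches were not recorded in the labels. After the control probe sets were seen to differ between arrays, their 62 signals were grouped into 4 batches by Ward clustering, and the 45 spike-in probe sets alone into 3. The batches were added to the fit as a block. Other alternatives set beforehand were a block by replicate number or by the first digit of the label number, a fit of only the arrays compared, an intensity trend with a robust prior, other choices of probe set, leaving out dim genes, median centring, quantile normalization, a stricter adjusted p of 0.01, an added 2-fold change, either kind of control alone, the line as the unit or as a random block, and leaving out each array. The block of batches, M5 represented by its first array alone, and leaving out chromosome 3 were added after the data had been seen.

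Splits of the arrays into other groups of the same sizes, random groupings of arrays into batches, and 100 simulations of unchanged groups against the same controls were used as tests. The code was tested on simulated data in which 200 of 11963 genes were changed by known amounts. Without simulated batches, 99% of 2-fold changes in the mean of the lines were found, with 5.24% false calls. With the batch shifts of the real arrays added, 30.8% of 266 simulated calls in M5 were false without the block and 5.1% of 196 with it. Some M5 arrays form a batch without other groups, so its shift cannot be told apart from a difference between M5 cultures. The simulation treated that shift as batch, as the block does. These rates therefore do not show how many real M5 calls without the block are false. A raised list and a lowered chromosome 3 were found with 0 others called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.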

Results

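Gene expression was measured on 13 Affymetrix oligonucleotide arrays of human non-small cell lung carcinoma cells. Control cells filled 4 arrays, 2 from cells without a luciferase reporter and 2 from cells carrying it. The other 9 arrays held 3 bone-metastatic lines, named M1, M4 and M5, with 3 arrays per line. According to the labels, these lines were isolated from bone after control cells had been injected into the hearts of mice, and their metastatic activity was then assessed by reinjection. RNA from 3 groups of cells was pooled for every array. The arrays are labelled as biological replicates, and p-values measure only the spread between them. The title of the series asks for a gene signature of bone colonisation, so each line, and the mean of the lines, was compared with control. Across genes, which are not independent replicates, pairs of arrays correlated with r between 0.975 and 0.998. No pair of arrays held equal values, since the smallest median absolute difference was 0.0932 log2 units. The number of arrays limits the precision.

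The Affymetrix control probe sets, which report added spike-in transcripts and hybridisation rather than the cells' own genes, divided the arrays into 4 batches. Batch 1 held control without luciferase replicate 1, control with luciferase replicate 1 and M1 replicate 2. Batch 2 held both second control arrays and the first arrays of M1, M4 and M5. Batch 3 held M4 replicates 2 and 3 with M1 replicate 3, and batch 4 held only M5 replicates 2 and 3. Of the 13 arrays, 13 were closest across all genes to an array of their own batch, whereas 4 were closest to an array of their own group. The 2 kinds of control counted as separate groups here, and each control array was closest to the control array of the other kind in its batch. Batches accounted for 63.9% of the sum of squares across genes, and the 5 groups for 41.9%. Because batches 1 to 3 held more than 1 group, every comparison is given from the deposited values without a batch term and again with the 4 batches as a block. Batch 4 held M5 alone, so its 2 arrays bear on M5 against control only without the block.

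**Figure D1:**
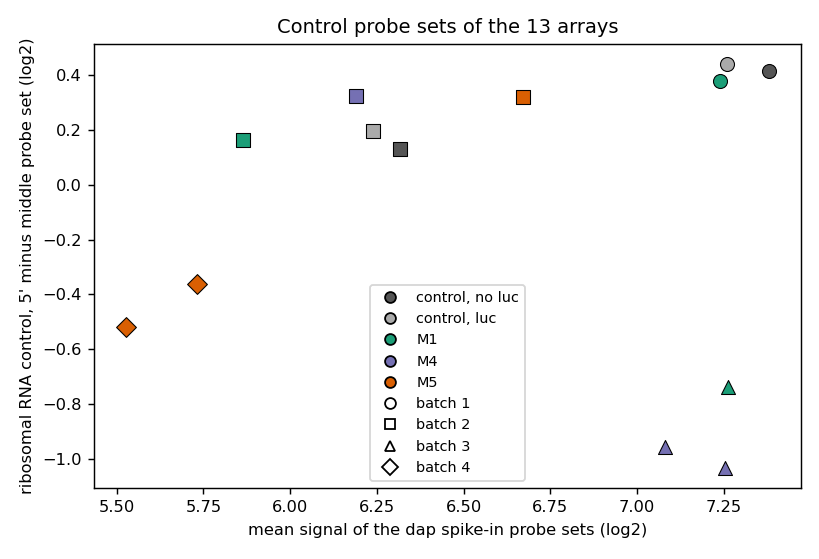
Signals of control probe sets on the 13 arrays. The horizontal axis gives the mean log2 signal of the dap spike-in probe sets and the vertical axis the 5' minus the middle probe set of a ribosomal RNA control (log2). Each point is 1 array, coloured by group and shaped by batch. M5 replicates 2 and 3 lie at 5.53 and 5.73 on the horizontal axis, apart from M5 replicate 1 at 6.67.

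Taken as the mean of the 3 bone-metastatic lines, SORBS2, an adaptor protein of actin stress fibres, rose 2.53-fold against control (log2 difference 1.34 ± 0.18, SE; limma adjusted p = 0.0447). Its signal went from 6.94 ± 0.52 (log2, SD, n = 4) in control to 8.28 ± 0.28 (SD, n = 9), and all 9 metastatic arrays lay above all 4 control arrays. A second SORBS2 probe set, with a mean signal of only 3.99, was at 0.17 (unadjusted p = 0.1255), so the rise rests on 1 probe set. CRYBG1, a member of the crystallin superfamily, rose 1.78-fold (0.83 ± 0.12, adjusted p = 0.0455), from 6.97 ± 0.29 (SD, n = 4) to 7.80 ± 0.40 (SD, n = 9). IGFBP3, a secreted protein that binds insulin-like growth factors, fell 1.67-fold (-0.74 ± 0.10, adjusted p = 0.0447), from 10.56 ± 0.30 to 9.82 ± 0.18. SORBS2 and CRYBG1 were chosen after their values were seen. Within batch 2, SORBS2 differed from control by 0.75 log2 units in M1, 0.69 in M4 and 1.24 in M5, CRYBG1 by 1.39, 0.87 and 1.00, and IGFBP3 by -0.77, -0.26 and -0.61. Within batch 1, M1 differed from control by 1.22, 1.08 and -0.70 for these genes.

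These 3 genes were the only calls for the mean of the lines out of 11963 genes, with 976 at an unadjusted p under 0.05. With the line as a random block or 1 mean per line as the unit, 0 genes were called (752 and 874 at an unadjusted p under 0.05). With the batches as a block, 35 genes rose and 28 fell, with 1159 at an unadjusted p under 0.05, and 3 were called in the same direction in both fits. The M5 part of this mean rests on M5 replicate 1 alone with the block. Of these 63 genes, 15 were called in M1 and 11 in M4. Without the block, leaving out single arrays gave 292 genes without M5 replicate 1, 13 without M1 replicate 2 and 1 without control with luciferase replicate 2. The count was 0 without control without luciferase replicate 1 or 2, control with luciferase replicate 1, M1 replicate 1, M4 replicate 2 or 3, or M5 replicate 2, with 610 to 905 genes at an unadjusted p under 0.05. Genes with all 9 metastatic arrays above all 4 control arrays numbered 33, and 39 had them all below. For both directions together, chance gives 0.28% of genes or 33.5 genes, fewer than these 2 counts combined. That value takes any 4 arrays as equally likely to be the controls, while batches 3 and 4 held metastatic arrays only.

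Several genes with known roles in tumour cells were called with the batch block but not in the fit of all arrays without it. Without the block, leaving out 1 array called ALDH1A1 in 4 of 13 fits, FBN2 in 2, and ABCG2, CD36 and CHRNA9 in 1 each. ALDH1A1, an aldehyde dehydrogenase of retinoic acid synthesis, rose 3.01-fold (log2 1.59 ± 0.10, SE; adjusted p = 5.37e-05), and the fit without batches gave 2.04 ± 0.31 (adjusted p = 0.0522). Its size depended on the kind of control: without the block it was 0.87 against controls without luciferase and 3.22 against those with it, neither called. ABCG2, a drug efflux transporter, rose 1.93-fold (adjusted p = 0.00192, against 0.0605 without the block). JAG1, a ligand of Notch receptors, rose 1.86-fold (adjusted p = 0.00242 and 0.747), while its other probe sets, without the block, were at -0.00092, 0.038 and 0.72. With the block JAG1 was at 0.41 in M1 and 0.23 in M4, neither called, and at 2.03 in M5, which rests on M5 replicate 1 alone. Without the block its mean over the lines was 0.46, and 0.25 without that array. FBN2, a microfibril protein of the extracellular matrix, fell 4.97-fold (log2 -2.31 ± 0.27; adjusted p = 0.00301 and 0.0684). Without the block FBN2 was at -1.67 in M1, 0.14 in M4 and -4.03 in M5, so the fall was not shared by M4. IL6, a cytokine that acts on bone resorption, fell 3.28-fold (-1.71 ± 0.32; adjusted p = 0.0455 and 0.955), and the chemokine CXCL1 fell 2.19-fold (-1.13 ± 0.13; adjusted p = 0.0025 and 0.981). Without the block IL6 was at -0.22 and CXCL1 at -0.073. Leaving out single arrays turned their signs, IL6 ranging from -0.50 without control without luciferase replicate 1 to 0.0705 without M4 replicate 1. CXCL1 ranged from -0.45 without control without luciferase replicate 1 to 0.31 without control without luciferase replicate 2. Within batch 2, IL6 differed from control by -2.23 in M1, -1.82 in M4 and -2.20 in M5, and within batch 1 by -1.03 in M1. With the block the nicotinic receptor subunit CHRNA9 rose 4.00-fold and the fatty acid receptor CD36 2.63-fold (both adjusted p = 5.7e-05), but these folds are not exact. On every control array both signals lay below the lower quartile of the array, with control means of 3.70 and 4.09. Without the block they were not called, at 1.32 ± 0.33 and 1.08 ± 0.30 (adjusted p = 0.237 and 0.323). With the block CHRNA9 was at 1.30 in M1, 0.74 in M4 and 3.97 in M5 and CD36 at 0.99, 0.04 and 3.16, the M5 values resting on M5 replicate 1 alone. Both were chosen after their values were seen, and M5 differed from M4 in both by the direct test with the block (adjusted p = 9.48e-05 and 5.19e-06).

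**Figure D2:**
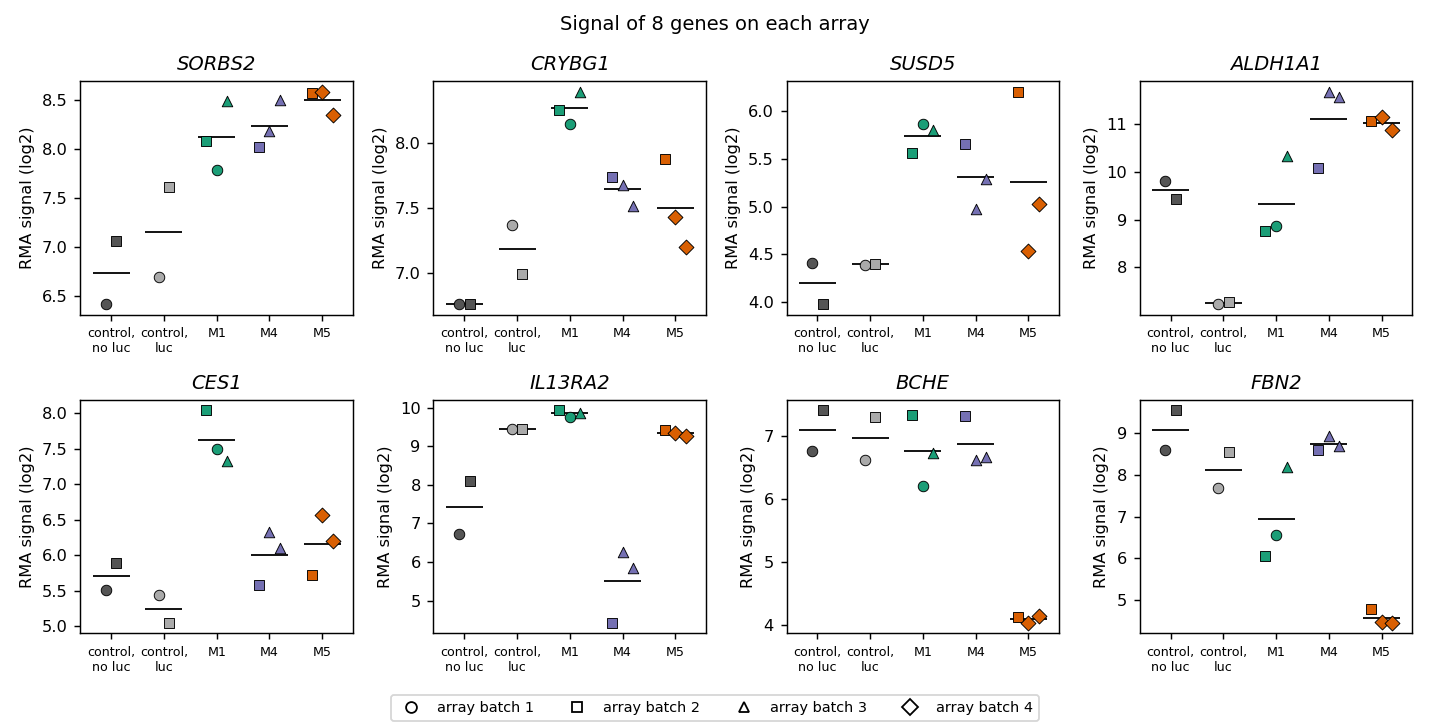
Log2 signal of 8 genes on each of the 13 arrays, by group, with points shaped by batch and horizontal bars at the group means. IL13RA2 lies between 4.43 and 6.26 on the M4 arrays, and FBN2 and BCHE lie lowest on the 3 M5 arrays.

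The fixed gene lists were then examined for the mean of the lines. Of the 29 lists with enough measured members to test, 0 were called by camera without the block, with 3 at an unadjusted p under 0.05, and 0 were called with an estimated correlation. With the block, 4 lists were called and 0 with an estimated correlation. The list of NF-kappaB targets and inflammatory cytokines fell with the block, with 2 of 38 measured members down, IL6 and CXCL1, 36 not passing, and 5 down when adjusted over the list alone. Its median was -0.21 and its mean -0.31 log2 units (camera adjusted p = 9.07e-06), against an adjusted p of 0.37 with an estimated correlation. Without the block its median was -0.00397 and 0 members passed, and 0 also passed when adjusted over the list alone. Within batch 2 its median was -0.10 in M1, -0.22 in M4 and -0.20 in M5, and within batch 1 it was -0.14 in M1.

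Axon guidance receptors and ligands also fell with the block (median -0.098, 40 measured, adjusted p = 0.0456), a call lost at adjusted p = 0.287 with an estimated correlation. Their only called member was the ephrin receptor EPHA2, which fell 1.42-fold (adjusted p = 0.0473), and 2 fell when adjusted over the list alone, with or without the block. Within batch 2 the list median was 0.043 in M1, -0.070 in M4 and -0.13 in M5, and within batch 1 it was 0.032 in M1. Without the block the median was 0.00868 and the list was not called. The Notch pathway rose (median 0.038, 16 measured, JAG1 up and 15 not passing, 2 up when adjusted over the list alone; adjusted p = 0.0456, and adjusted p = 0.287 with an estimated correlation). Its within-batch medians in batch 2 were 0.052, 0.052 and 0.050 in M1, M4 and M5, and 0.019 in batch 1 for M1. Without the block its median was 0.11 and it was not called. NRF2 targets and xenobiotic metabolism rose with the same pair of adjusted p-values, 0.0456 and 0.287 with an estimated correlation, from a median of 0.028 over 38 genes. ALDH1A1, ABCG2 and the vitamin D hydroxylase CYP24A1 (1.64-fold from a control mean of 3.68, below the lower quartile of every control array, adjusted p = 0.0473) rose, the prostaglandin-forming aldo-keto reductase AKR1C3 fell 1.40-fold (adjusted p = 0.0107), and 34 did not pass. The counts adjusted over the list alone were 3 up and 1 down in both fits, while without the block the list median was -0.018, its mean 0.058 and 0 members passed.

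Among lists tied to bone metastasis, osteolysis and bone metastasis factors (33 measured) held 0 called members without the block. With it JAG1 rose, and IL6, the matrix protein CCN1 (1.72-fold, adjusted p = 0.00231) and its relative CCN2 (1.63-fold, adjusted p = 0.0209) fell, with 29 not passing and 1 up and 3 down adjusted over the list alone. The shift of this list was not called (camera adjusted p = 0.138), its median being -0.034 and its mean -0.14. In the epithelial identity and junction list (28 measured), the tight junction protein CLDN1 fell 1.80-fold with the block (adjusted p = 0.0194), 27 did not pass, and 2 fell adjusted over the list alone. Without the block the mean of CLDN1 over the lines was -0.52, not called, with -0.22 in M1, 0.05 in M4 and -1.40 in M5. Within batch 2 it differed from control by -0.64 in M1, -0.48 in M4 and -1.81 in M5, and within batch 1 by -0.19 in M1. CLDN1 lies on chromosome 3, whose genes fell together in M5. The mesenchymal and EMT list (34 measured) held 0 called members in either fit. Adjusted over the list alone, 2 rose and 2 fell without the block and 4 rose and 1 fell with it, S100A4 being at 0.85 ± 0.16 (adjusted p over all genes = 0.0528). Basement membrane and matrix glycoproteins (29 measured) had FBN2 and the proteoglycan SPOCK1 (2.24-fold, adjusted p = 0.0226) down with the block and 27 not passing, with 2 down adjusted over the list alone without the block and 3 with it (camera adjusted p = 0.0694). In the TGF-beta response list (31 measured), CCN2 and the receptor TGFBR2 (1.64-fold, adjusted p = 0.0209) fell with the block and 29 did not pass, and adjusted over the list alone 4 rose and 3 fell. Its median was 0.026, its mean -0.026 and its camera direction up.

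The list of EGFR family, ligands and MAPK feedback genes (39 measured) had IGFBP3 down in both fits and 38 not passing, with 1 down adjusted over the list alone without the block and 2 with it. Adhesion molecules and cadherins (37 measured) had MCAM up with the block and 36 not passing, and adjusted over the list alone 1 rose without the block and 2 rose and 1 fell with it. No member was called in either fit among extracellular proteases and inhibitors (37 measured), integrins (23), the Wnt pathway (27), interferon-stimulated genes (35), MHC and antigen presentation (26), the hypoxia response (31), glycolysis (19), cholesterol and lipid synthesis (25), lung lineage genes (23), the cell cycle (44), p53 targets (21), the unfolded protein and heat shock response (22) and immediate early genes (19). Adjusted over the list alone, these 13 lists held 0 called members except 2 Wnt genes down without the block, 1 hypoxia gene up and 1 down without the block, 1 up and 2 down with it, and 2 immediate early genes down with it. The lowest camera adjusted p among all tested lists without the block was 0.351. Markers of other cell types that bone lesions hold were not called in either fit: fibroblasts and marrow stroma (14 measured), osteoblasts (7), osteoclasts (5), haematopoietic cells (17) and endothelial cells (11). Adjusted over the list alone, 1 osteoclast marker rose without the block and 1 stromal marker with it. The lines came from bone of mice, where host cells are mouse cells. These human markers therefore do not test whether host cells were carried over.

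TCF4, a basic helix-loop-helix transcription factor, PRKD3, a protein kinase D, MCAM, a cell adhesion molecule, and SUSD5, a sushi-domain protein, were singled out by the published study on these samples, so their direction here is not independent evidence. SUSD5 rose 2.99-fold with the block (log2 1.58 ± 0.16, SE; adjusted p = 0.00126), MCAM 2.53-fold (1.34 ± 0.14, adjusted p = 0.00192) and PRKD3 2.15-fold (1.11 ± 0.09, adjusted p = 0.000144). TCF4 was at 0.80 ± 0.15 with the block (adjusted p = 0.0505) and was not called. Without the block 0 of the 4 were called, at log2 differences of 1.14 ± 0.24 for SUSD5, 1.09 ± 0.22 for MCAM, 0.66 ± 0.21 for PRKD3 and 0.65 ± 0.16 for TCF4 (adjusted p = 0.133, 0.109, 0.429 and 0.228). Adjusted over the list alone, 4 of 4 rose in either fit. All 9 metastatic arrays lay above all 4 control arrays for MCAM and SUSD5. Within batch 2, M1, M4 and M5 differed from control by 1.37, 1.47 and 2.02 for SUSD5, 2.07, 1.29 and 1.40 for MCAM, 1.02, 0.85 and 1.61 for PRKD3, and 0.91, 0.93 and 1.02 for TCF4. Within batch 1, M1 differed by 1.46, 1.27, 0.82 and 0.48.

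Genes called in the same direction in all 3 lines numbered 0 without the block by limma, with 78 at an unadjusted p under 0.05 in each line, and 1 with it, PRKD3, with 132 at an unadjusted p under 0.05. PRKD3 rose 1.89-fold in M1, 1.78-fold in M4 and 2.98-fold in M5 with the block (adjusted p = 0.00315, 0.0179 and 0.000235). The M5 value with the block rests on M5 replicate 1 alone. Without the block PRKD3 in M5 was at 0.58, and at 0.13 without that array, neither called.

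In M1, CES1, a carboxylesterase, rose 4.42-fold against control (log2 2.15 ± 0.24, SE; adjusted p = 0.00769), from 5.48 ± 0.35 (SD, n = 4) to 7.62 ± 0.38 (SD, n = 3). HCLS1, a cortactin-related actin regulator best known from blood cells, rose 2.57-fold (1.36 ± 0.16, adjusted p = 0.00769) and CRYBG1 rose 2.46-fold (1.30 ± 0.15, adjusted p = 0.00769). HCLS1 was chosen after its values were seen, and its fold is not exact, since its control mean was 3.94 and 3 of the 4 control arrays held it below their lower quartile. With the block all 3 were called, at 2.11 ± 0.23, 1.43 ± 0.16 and 1.29 ± 0.12. Within batches 2 and 1, CES1 in M1 differed from control by 2.57 and 2.01, HCLS1 by 1.55 and 1.60, and CRYBG1 by 1.39 and 1.08.

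In total 3 genes rose and 0 fell in M1 without the block, with 368 genes at an unadjusted p under 0.05, and 17 rose and 11 fell with it. The genes called with the block included MCAM (3.27-fold, adjusted p = 0.00202), SUSD5 (2.90-fold, adjusted p = 0.00353), the fibrillar collagen COL3A1 (2.69-fold, adjusted p = 0.00521) and HES1, a transcriptional target of Notch (1.73-fold, adjusted p = 0.0221). FBN2 fell 4.18-fold (adjusted p = 0.0148) and IGFBP3 1.60-fold (adjusted p = 0.0108). By list, 3 of the 4 genes the study singled out rose with the block and 0 without it. In each of the mesenchymal, Notch, adhesion and stromal marker lists 1 gene rose with the block, and in each of the basement membrane and EGFR lists 1 fell. Without the block 0 lists were called by camera, with 2 at an unadjusted p under 0.05. With it the NF-kappaB list fell (median -0.17, adjusted p = 0.00344, and adjusted p = 0.409 with an estimated correlation), although 0 of its 38 members passed and 2 fell adjusted over the list alone. The NRF2 list rose (median 0.022, adjusted p = 0.0411, and adjusted p = 0.408 with an estimated correlation), with 0 members passing and 4 up and 1 down adjusted over the list alone. Without single arrays the count of M1 genes was 14 without M5 replicate 1 and 0 without control without luciferase replicate 1 or M1 replicate 1 (limma, with 333 and 395 at an unadjusted p under 0.05).

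In M4, IL13RA2, a decoy receptor for interleukin 13, fell 7.58-fold against control (log2 -2.92 ± 0.37, SE; adjusted p = 0.0187), to 5.51 ± 0.96 (SD, n = 3). It also lay below M1 by 4.34 ± 0.40 (adjusted p = 0.00098) and below M5 by 3.83 ± 0.40 (adjusted p = 0.000437). The control arrays themselves were spread, at 6.73 and 8.11 without luciferase and 9.43 and 9.45 with it, and against those without luciferase IL13RA2 in M4 was at -1.91, not called. CRIP1, a LIM-domain protein, rose 3.06-fold (1.61 ± 0.15, adjusted p = 0.000909), ALDH1A1 rose 6.35-fold (2.67 ± 0.40, adjusted p = 0.0404), and ABCG2 rose 2.49-fold (1.32 ± 0.18, adjusted p = 0.0247). ALDH1A1 in M4 was at 1.49 against controls without luciferase, not called, and at 3.85 against those with it, called. RAB31, a GTPase of vesicle transport, fell 2.25-fold (-1.17 ± 0.19, adjusted p = 0.0448). With the block IL13RA2 was at -3.58 ± 0.41, CRIP1 at 1.65 ± 0.15, ALDH1A1 at 1.69 ± 0.13, ABCG2 at 1.18 ± 0.13 and RAB31 at -1.38 ± 0.15, all called. Within batch 2 these genes differed from control by -4.35, 1.81, 1.72, 1.31 and -1.25. CRIP1 was chosen after its values were seen.

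In total 8 genes rose and 3 fell in M4 without the block, with 827 at an unadjusted p under 0.05, and 12 rose and 6 fell with it, 8 genes being common to both in the same direction. The calls of RBM47, an RNA-binding protein, MECOM, a zinc finger transcription factor, and PLEK2, a pleckstrin, ended with the block (adjusted p = 0.12, 0.106 and 0.0902), going from 0.66 ± 0.10 to 0.56 ± 0.12, from 1.00 ± 0.16 to 0.77 ± 0.15 and from -1.35 ± 0.22 to -0.96 ± 0.18. These 3 genes were chosen after their values were seen. With the mean of its probe sets MECOM was at 0.33 and not called. Of the NRF2 list, ALDH1A1 and ABCG2 rose in both fits, AKR1C3 fell with the block (-0.59 ± 0.09, adjusted p = 0.0312), and adjusted over the list alone 4 rose and 1 fell without the block. SPOCK1, of the basement membrane list, fell 3.12-fold with the block (adjusted p = 0.0308). PRKD3 was the 1 gene called with the block of the 4 that the study singled out, of which 0 were called without it. Without the block 0 lists were called by camera, with 3 at an unadjusted p under 0.05. With it the NF-kappaB list fell, with a median of -0.15 against 0.081 without it (adjusted p = 0.00537, and adjusted p = 0.703 with an estimated correlation). MHC and antigen presentation fell too (median -0.083, adjusted p = 0.00998, and adjusted p = 0.581 with an estimated correlation), and 0 members of either list passed. The MHC median without the block was 0.00842, not called, and -0.081 for M4 within batch 2. The count of M4 genes was 32 without M5 replicate 1 and 1 without control with or without luciferase replicate 2 or M4 replicate 3. It was 2 without the first control array of either kind or M4 replicate 2, 3 without M1 replicate 1, and 5 without M5 replicate 3.

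In M5, FBN2 fell 16.4-fold against control (log2 -4.03 ± 0.41, SE; adjusted p = 0.000597), from 8.60 ± 0.76 (SD, n = 4) to 4.56 ± 0.18 (SD, n = 3). BCHE, the serum cholinesterase, fell 7.65-fold (-2.93 ± 0.27, adjusted p = 0.0004), and ROBO1, a receptor of Slit guidance cues, fell 3.73-fold (-1.90 ± 0.17, adjusted p = 0.0004). VAMP8, a vesicle fusion protein, fell 3.10-fold and the neuronal transmembrane protein SLITRK5 3.03-fold. SERPIND1, the thrombin inhibitor heparin cofactor II, rose 10.9-fold (3.45 ± 0.43, adjusted p = 0.00244), from 4.17 ± 0.12 (SD, n = 4) to 7.62 ± 0.35 (SD, n = 3). The phosphatase PPEF1 rose 4.42-fold, the bile acid-binding protein FABP6 3.21-fold, the homeobox factor PRRX2 2.13-fold and the glutathione transferase GSTA4 2.11-fold. The folds of BCHE and PPEF1 are not exact, since BCHE on all M5 arrays and PPEF1 on all control arrays lay below the lower quartile of the array, and SERPIND1 did on 2 control arrays. With the mean of their probe sets FBN2 was at -2.02 and SLITRK5 at -0.97, both called. With a block by the first digit of the label number SERPIND1 was at 2.21 and not called. VAMP8 in M5 was at -2.50 against controls without luciferase, called, and at -0.77 against those with it, not called. All 10 genes also differed from M1 and from M4 in the same direction without the block.

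All 10 remained called against control with the block, FBN2 at -4.12 ± 0.43, BCHE at -3.34 ± 0.15, ROBO1 at -1.78 ± 0.23, SERPIND1 at 3.09 ± 0.23, PPEF1 at 2.85 ± 0.18 and FABP6 at 0.98 ± 0.14. Within batch 2 the M5 array differed from control by -4.28 for FBN2, -3.25 for BCHE, -1.93 for ROBO1, -1.99 for VAMP8 and -1.45 for SLITRK5. It differed by 3.06 for SERPIND1, 2.72 for PPEF1, 1.02 for FABP6, 0.71 for PRRX2 and 1.25 for GSTA4. ALDH1A1 rose 6.02-fold in M5 (adjusted p = 0.00723), and with the block 6.50-fold (adjusted p = 5.46e-06), but without the block it was at 1.41 against controls without luciferase, not called, and at 3.77 against those with it, called. JAG1 and PRKD3 were called in M5 with the block but not without it, at 4.09-fold and 2.98-fold (adjusted p = 9e-05 and 0.000235, against 0.345 and 0.281 without it). Their signals differed between the M5 arrays, JAG1 at 8.36, 6.40 and 6.50 and PRKD3 at 10.37, 9.14 and 8.89 on replicates 1, 2 and 3.

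In total 63 genes rose and 221 fell in M5 without the block, with 2156 at an unadjusted p under 0.05. With the block, where only M5 replicate 1 informs M5 against control, 115 rose and 122 fell, and 88 genes were called in the same direction in both fits, which share their arrays. Leaving out M5 replicate 1 raised the count to 3062, and it was 54 without M5 replicate 2 and 55 without M5 replicate 3. It was 77 and 80 without control without luciferase replicates 1 and 2, 76 and 84 without control with luciferase replicates 1 and 2, and 165 and 177 without M4 replicates 2 and 3.

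Genes of chromosome 3 fell together in M5. Of the 221 genes that fell, 141 (63.8%) lie on chromosome 3, which holds 655 (5.48%) of the genes tested (Fisher's exact test, 2.73e-125, across genes, which are not independent). Among chromosome 3 genes above the median signal, the median log2 difference was -0.55, against -0.028 for the rest of the genome, and 96.1% were lower. Camera called the chromosome with adjusted p = 1.17e-25, and adjusted p = 2.28e-05 with an estimated correlation. With the block the median was -0.38 (adjusted p = 6.88e-20, and adjusted p = 0.00813 with an estimated correlation), and 71 of 122 falling genes lay there. Replicate 1 of M5 shares batch 2 with control, M1 and M4 arrays. Over chromosome 3 genes above the median signal (335 of 655), the median shift was -0.39, -0.59 and -0.56 on M5 replicates 1, 2 and 3. On the other 10 arrays it lay between -0.024 and 0.043. BCHE, ROBO1, CLDN1, ALCAM, PLXNA1, XPC, MCM2, ETV5 and TGFBR2 are on this chromosome. The count of 141 depended on single arrays, from 31 without M5 replicate 3 and 33 without M5 replicate 2 to 285 without M5 replicate 1. Leaving out 1 control array gave 46 to 53. Outside this chromosome, 62 genes rose and 80 fell in M5 without the block. With chromosome 3 left out of the fit and the adjustment, 39 genes were called in M5. Most of the calls outside it thus passed only with its genes included.

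**Figure D3:**
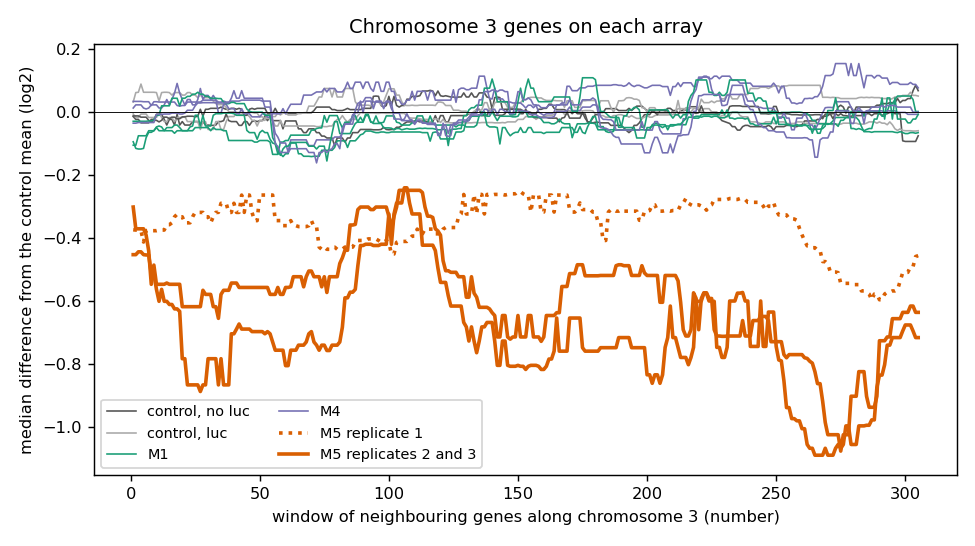
Medians of log2 signal, relative to the mean of the control arrays, over windows of 31 neighbouring chromosome 3 genes, ordered by gene position. Only genes above the median signal were used, and values are not set against the other chromosomes of the same array. Each line is 1 array, coloured by group. In all 3 M5 arrays each of the 305 windows lies below 0, the highest at -0.241, and the lowest window of any other array is at -0.162.

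The fixed lists held few called members in M5, several of them on chromosome 3. Axon guidance genes fell in 3 of 40 cases without the block, ROBO1, the semaphorin receptor PLXNA1 (1.70-fold, adjusted p = 0.00723) and EPHA2 (1.78-fold, adjusted p = 0.0178), with 37 not passing and 7 down adjusted over the list alone. Without probe sets marked as less specific PLXNA1 was at -0.071, and with the mean of its probe sets at -0.42, neither called. EPHA2 was at -0.45, not called, with a block by the first digit of the label number. Their list median was 0.00885 and their mean -0.11, and camera called the list with the block but not without it (median -0.14, adjusted p = 0.00769, and adjusted p = 0.276 with an estimated correlation). Of the osteolysis list, the adhesion molecule ALCAM (1.87-fold, adjusted p = 0.00404), the neutrophil chemokine CXCL8 (1.53-fold, adjusted p = 0.025) and the Wnt inhibitor DKK1 (1.79-fold, adjusted p = 0.0287) fell, 30 did not pass, and 5 fell adjusted over the list alone. With the block, where 1 M5 array informs the fit, neither CXCL8 nor DKK1 was called (adjusted p = 0.0928 and 0.277). CXCL8 went from -0.61 ± 0.13 to -0.55 ± 0.15 and DKK1 from -0.84 ± 0.18 to -0.54 ± 0.22. S100A4, a calcium-binding protein of motile cells, was the 1 mesenchymal gene of 34 that rose (2.36-fold, log2 1.24, adjusted p = 0.0476, and 0.0186 with the block). This call was lost in 15 of 27 alternatives, 9 of them with 1 array left out, and with a block by the first digit of the label number the difference was 0.25. CLDN1 was the 1 epithelial gene of 28 that fell (2.63-fold, adjusted p = 0.00723), and counts adjusted over the list alone were the same for these 2 lists. Of the basement membrane list, FBN2 and AGRN, the heparan sulfate proteoglycan agrin, fell, the latter 1.35-fold (-0.43 ± 0.09, adjusted p = 0.0291, and -0.43 ± 0.11, 0.0831 with the block), and 3 fell adjusted over the list alone. In the Wnt list DKK1, FZD2 and FZD6, both Frizzled receptors, fell (1.40-fold and 1.77-fold, adjusted p = 0.0374 and 0.0237), with 3 down adjusted over the list alone. Neither Frizzled receptor was called with the block (adjusted p = 0.121 and 0.34), where FZD2 went from -0.49 ± 0.11 to -0.43 ± 0.12 and FZD6 from -0.82 ± 0.17 to -0.25 ± 0.12.

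Cell cycle genes (44 measured) and p53 targets (21 measured) fell as lists in M5 without the block, with medians of -0.11 and -0.10 and camera adjusted p = 0.0264 for each, and adjusted p = 0.812 with an estimated correlation. Neither was called with the block (adjusted p = 0.937 for each), where the p53 median was 0.027, its mean -0.047 and its camera direction up. Without the block the cell cycle median ranged from -0.13 without control with luciferase replicate 1 to -0.0012 without M5 replicate 2, and leaving out 3 of the 13 arrays ended the call. The p53 median ranged from -0.24 without M5 replicate 1 to -0.049 without M5 replicate 3, and leaving out 2 arrays ended the call. The replication licensing factor MCM2 fell 1.47-fold (adjusted p = 0.0171, and 0.0239 with the block) as the only called cell cycle gene, also adjusted over the list alone. The p53 targets XPC, a DNA damage sensor, and TP53I3, an oxidoreductase, fell 1.59-fold and 1.68-fold (adjusted p = 0.00723 and 0.0415, and 0.0819 and 0.484 with the block), with 4 down adjusted over the list alone. With the block XPC went from -0.67 ± 0.10 to -0.51 ± 0.13 and TP53I3 from -0.75 ± 0.17 to -0.21 ± 0.13. The NF-kappaB list had CXCL8 and IL18, a cytokine of the interleukin 1 family, down (IL18 2.25-fold, adjusted p = 0.0189) and 2 down adjusted over the list alone. Its median was 0.039 without the block, where its mean was -0.073, and -0.18 with it (adjusted p = 0.000436, and adjusted p = 0.445 with an estimated correlation). With the block IL18 was not called (adjusted p = 0.247), going from -1.17 ± 0.23 to -0.67 ± 0.26. Of the NRF2 list ALDH1A1 rose and AKR1C3 and ALDH3A2, a fatty aldehyde dehydrogenase, fell (adjusted p = 0.0147 and 0.0293), with 2 up and 4 down adjusted over the list alone. The calls of AKR1C3 and ALDH3A2 ended with the block (adjusted p = 0.0704 and 0.258), at -0.43 ± 0.11 after -0.60 ± 0.11 and -0.29 ± 0.12 after -0.46 ± 0.10.

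IGFBP3, the phosphatase DUSP1 and the transcription factor ETV5 fell in the EGFR list in M5 (1.75-fold, 1.85-fold and 1.66-fold), and 3 fell adjusted over the list alone. With the block DUSP1 was not called (adjusted p = 0.086), although its difference went from -0.89 ± 0.19 to -1.07 ± 0.28, since its error grew. SMAD3, which transduces TGF-beta signals, rose 2.26-fold (1.18 ± 0.26, adjusted p = 0.0374, and 0.73 ± 0.21, 0.116 with the block), and 1 rose and 6 fell of the TGF-beta list adjusted over the list alone. In the lung lineage list PDPN rose (log2 0.59, from below the lower quartile of every control array) and ETV5 fell, with 2 up and 2 down adjusted over the list alone, and in the immediate early list DUSP1 and JUN fell, with 4 up and 2 down adjusted over the list alone. Without probe sets marked as less specific JUN was at -0.083, and with the mean of its probe sets at -0.27, neither called. The gelatinase MMP9, an osteoclast marker and a protease, rose 1.48-fold (adjusted p = 0.0407), and adjusted over the list alone 4 proteases rose and 5 fell and 1 osteoclast marker rose. Single genes also passed in the integrin, interferon, unfolded protein and adhesion lists, where ITGA2 fell (-0.58), LGALS3BP rose (0.50), SEL1L fell (-0.63) and ALCAM fell. Adjusted over the list alone the counts were 1 down, 1 up, 1 down and 2 down. The calls of PDPN, MMP9, ITGA2, LGALS3BP and SEL1L ended with the block (adjusted p = 0.248, 0.287, 0.209, 0.221 and 0.641), where their differences were 0.35 ± 0.13, 0.40 ± 0.17, -0.38 ± 0.14, 0.32 ± 0.12 and -0.15 ± 0.13. Of the genes the study singled out, 0 of 4 were called in M5 without the block and 3 with it, and 3 and 4 rose adjusted over the list alone.

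Between the lines, M5 stood furthest from the others. M5 lay below M4 by 4.17 ± 0.43 log2 units for FBN2 and by 2.04 ± 0.18 for MXRA7, a matrix remodelling-associated protein, and above it by 3.83 ± 0.40 for IL13RA2 (adjusted p = 0.000437 for each). IL18 lay 2.15 ± 0.24 lower in M5 than in M4 (adjusted p = 0.000797). HCLS1 lay below the lower quartile on every M4 and M5 array. Against M1, M5 had lower HCLS1 (-1.52 ± 0.18, adjusted p = 0.00185), COL3A1 (-1.72 ± 0.32, adjusted p = 0.0226) and CES1 (-1.46 ± 0.25, adjusted p = 0.0194). With the block these values were -3.37, -1.54, 4.40 and -1.45 against M4 and -1.79, -1.54 and -1.89 against M1, all called. M4 differed from M1 in IL13RA2, in HCLS1 (-1.65 ± 0.18, adjusted p = 0.00295) and in CRIP1 (1.19 ± 0.16, adjusted p = 0.0186). Within batches 2 and 3, M4 minus M1 was -5.50 and -3.80 for IL13RA2, -2.09 and -1.16 for HCLS1 and 1.43 and 1.00 for CRIP1.

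The counts were 1 up and 2 down for M4 against M1, 29 up and 118 down for M5 against M1, and 45 up and 213 down for M5 against M4. With the block they were 5 and 9, 99 and 94, and 120 and 101. Outside chromosome 3, 65 genes differed between M5 and M1 and 128 between M5 and M4 without the block. Without M5 replicate 1 the M5 counts became 2366 against M1 and 2443 against M4. For M5 against M1 they were 37 and 22 without M5 replicates 2 and 3, and 51, 46 and 59 without M1 replicates 1, 2 and 3. They were 83 without M4 replicate 2 or 3, 92 without control without luciferase replicate 1 or 2, and 93 without control with luciferase replicate 1 or 2. For M5 against M4 they were 124 and 71 without M5 replicates 2 and 3, and 162, 69 and 90 without M4 replicates 1, 2 and 3. M4 against M1 gave 7 genes without M1 replicate 3 and 6 without M5 replicate 1. Genes that changed in 1 line against control and differed from both other lines in the same direction numbered 1 in M1, 2 in M4 and 103 in M5, and 2, 4 and 105 with the block. Without the block, M5 against M1 had MHC and antigen presentation up and the NRF2, cell cycle and p53 lists down (the lowest adjusted p = 0.0315, and adjusted p = 0.682 with an estimated correlation). M5 against M4 had basement membrane genes down (adjusted p = 0.028) and p53 targets down (adjusted p = 0.000156), at adjusted p = 0.538 with an estimated correlation. With the block 0 lists were called by camera between the lines, with 3, 3 and 1 at an unadjusted p under 0.05.

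Controls with and without the luciferase reporter differed at few called genes. The labels name them as control cell lines, with 2 arrays of each kind. The reporter therefore cannot be told apart from other differences between these lines. With the block limma gave 709 genes at an unadjusted p under 0.05. With the block ALDH1A1 was 5.13-fold lower with the reporter (log2 -2.36 ± 0.13, SE; adjusted p = 1.49e-05) and VAMP8 3.30-fold lower (-1.72 ± 0.16, adjusted p = 0.00161). ALDH1A1 lay at 9.82 and 9.42 on the 2 arrays without luciferase and at 7.23 and 7.29 with it. Within batches 1 and 2 the differences were -2.58 and -2.13 for ALDH1A1 and -1.66 and -1.79 for VAMP8. Without the block limma called 0 genes, with 154 at an unadjusted p under 0.05, and these 2 genes had adjusted p = 1.00 and 0.145. The NF-kappaB list (adjusted p = 0.03) and interferon-stimulated genes (0.0455) were lower and the cell cycle list (0.0455) higher with luciferase, at adjusted p = 0.988 with an estimated correlation. With the block the NF-kappaB list alone was called (adjusted p = 0.0201, and adjusted p = 0.889 with an estimated correlation).

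Across genes, the log2 differences of the lines from the shared control correlated with r = 0.559 for M1 and M4, 0.342 for M1 and M5 and 0.329 for M4 and M5. Simulated unchanged groups against the same controls gave r = 0.428, and the covariances were 0.0159, 0.0142 and 0.0178, against 0.012 simulated. The simulation took arrays as independent and left out their batches. With the block r was 0.627, 0.298 and 0.231 for the same pairs. With each line compared with its own kind of control, so that no array was shared, r was 0.252 and 0.321 for M1 and M4, 0.18 and 0.156 for M1 and M5, and 0.223 and 0.165 for M4 and M5. With the controls split by replicate number instead, which also shares no array, r was 0.273 and -0.0457, 0.0401 and 0.035, and -0.00282 and 0.192 for the same pairs. Of the called genes 2 were up in both M4 and M5 without the block, ALDH1A1 and RBM47. Independent lists would share 0.0421, a value that leaves out the control arrays common to both comparisons. With the block 2 genes were up in both M1 and M4, against 0 without it. Overlaps with M5 in that fit rest on M5 replicate 1 alone.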

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

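The tests of array batch and of whole-chromosome dose on chromosome 3, the tests of differing lines, and all tests of M5 replicate 1 except the first test of its label were chosen only after the results were seen.

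Several genes differed between the lines in their change against control, by direct limma tests of the difference. IL13RA2 lay at -3.83 log2 units in M4 relative to M5. Relative to M1, M5 lay at 2.50 for SERPIND1, 1.70 for PPEF1, 0.76 for GSTA4, -2.37 for FBN2, -2.67 for BCHE and -1.45 for SLITRK5. Relative to M4, M5 lay at 1.53 for FABP6, 0.95 for PRRX2, -1.49 for ROBO1 and -1.48 for VAMP8. The PRRX2 difference between M5 and M4 was 0.59 ± 0.14 with the 4 batches as a block, where it was not called, after 0.95 ± 0.17 without it. The number of genes that differed was 3 between M4 and M1, 147 between M5 and M1 and 258 between M5 and M4. The chromosome 3 median in M5 was -0.50 relative to M1 and -0.55 relative to M4.

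Chromosome 3 genes were lower in M5. The array batch does not account for this, because M5 replicate 1, which shares its batch with control, M1 and M4 arrays, had a median shift of -0.3937. The signal level of the genes is excluded too, since the lowest median of 10000 gene sets matched on signal was 0.003891. The median of all 655 chromosome 3 genes, bright and dim, was -0.287. A lower dose of the whole chromosome in M5 is a candidate explanation, as the highest window in any M5 array was -0.241 and the lowest window in any other array -0.162. On M5 replicate 2, however, 232 of 240 chromosome 5 windows also lay below 0, the lowest at -0.299, with that chromosome's median shift at 0.01. On that array the windows alone cannot show that every part of chromosome 3 was lower. On M5 replicate 1 the highest chromosome 3 window was -0.253, and chromosome 5 windows lay between 0.028 and 0.317. DNA was not measured, so a regulatory cause remains open, and whether the selection in bone or the passage of the line brought the change was not tested.

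Few genes were called for the mean of the lines without array batches, 3 against 63 with the block of 4. Array batch may account for the difference, since 3 of 100 random groupings of the arrays gave as many calls as the real batches (median 0, highest 294). Differences between the lines stay open as an explanation, since 1.59% of the 63 genes were called in all 3 lines. That 61 of them had the same direction in all 3 cannot decide this, because the genes were picked on the mean of these same comparisons.

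M5 replicate 1 lay apart from M5 replicates 2 and 3, and the count for M5 was 284 with it and 3062 without it. A mislabelled array was tested by a prediction set beforehand, and the test came out on the side of a wrong label: of 1793 genes that set replicates 2 and 3 apart from M1 and M4, 49.9% lay on the M5 side in replicate 1. That share was 69.1% of 152 genes with 2-fold differences and 58.9% of 95 of these outside chromosome 3, but the genes had been picked from 2 arrays that form a batch of their own. The chromosome 3 shift of -0.3937, chosen as a test afterwards, excludes an array of M1, M4 or control, while an outside sample that shares the shift stays open. Array batch (r = 0.462 across genes with the same difference in M4, and 0.0257 to 0.233 in M1 and control) and a difference between M5 cultures cannot be told apart, since 0 arrays of other groups share the batch of replicates 2 and 3.

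The 3' control probe set for ribosomal RNA, which no gene test used but which helped to form the batches, read 5.96 and 5.68 on M5 replicates 2 and 3, above all control arrays, whose highest value was 4.86. Of 3151 probe sets with no gene or several genes, limma called 6 for the mean of the lines and 20 for M5 against control.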

How the results depend on the processing

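The blocks of array batches, M5 represented by its first array alone, and leaving out chromosome 3 were chosen only after the results were seen, as were the splits within batches. Gene and list results called without a block numbered 59, and 1001 of their 1605 alternatives kept the call and direction while 597 lost the call. Of 1713 alternatives of the 61 uncalled results, 1498 stayed uncalled and 199 gained a call. Among results called in at least 1 of the 2 fits compared, directions reversed 23 times, and signs changed 61 times where neither fit called the result. The number of arrays and the batches limit these counts, and where no cause is given, the cause was not tested.

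The replicate block, which adds the labels' replicate number, gave by limma 0 genes for the mean of the lines (550 at an unadjusted p under 0.05), 2 for M4, 106 for M5, 97 for M5 against M1 and 1 for luciferase. Replicate numbers did not pair the arrays throughout. Of the same-numbered pairs, 7 of 23 had residual correlations over 0.1 (median -0.075), against 19 of 44 pairs with different numbers (median 0.051). Still, 8 of 13 arrays correlated best with an array of their own number, and the numbers overlap with the batches in part. In pairs of the same batch, 14 of 15 were over 0.1.

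Fitting only the arrays compared, with fewer arrays for the spread, gave 5 genes for M1, 33 for M4, 29 for M5, 4 for M5 against M1 and 48 for M5 against M4. An intensity trend with a robust prior gave 13 for the mean of the lines and 20 for M4. The mean of probe sets gave 6 for the mean of the lines. Without probe sets marked as less specific the counts were 0 for the mean of the lines (605 unadjusted), 7 for M4, 175 for M5 and 145 for M5 against M4, and AGRN in M5 was at 0.0707, from another probe set. All probe sets gave 5 for the mean of the lines and 3 for M4, and leaving out the dim genes gave 5 and, for M4 against M1, 1. Median centring gave 0 (970 unadjusted) and quantile normalization 19 for the mean of the lines. At adjusted p under 0.01, a stricter limit, counts were 0 for the mean of the lines (976 at an unadjusted p under 0.05), 1 for M4, 45 for M5, 29 for M5 against M1 and 72 for M5 against M4. With an added 2-fold limit they were 1 for the mean of the lines, 52 for M5, 42 for M5 against M1 and 66 for M5 against M4.

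A block by the first digit of the label number gave by limma 0 genes for the mean of the lines and 0 for M1 (543 and 398 at an unadjusted p under 0.05), 3 for M4, 15 for M5, 96 for M5 against M1 and 1 for luciferase, with 3 lists called. In M5 it reversed the medians of the NF-kappaB list (-0.18), axon guidance (-0.13) and the cell cycle (0.041). With only the controls without luciferase, counts were 6 for the mean of the lines, 1 for M4 and 42 for M5. With only the controls with luciferase they were 0 for the mean of the lines (443 unadjusted), 1 for M1, 3 for M4 and 30 for M5, with 2 lists called. For the mean of the lines, the line as a random block gave 0 genes, as did 1 mean per line (752 and 874 unadjusted).

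The block of 4 batches gave 63 genes for the mean of the lines, 28 for M1, 18 for M4, 14 for M4 against M1 and 2 for luciferase, 1 shared gene and 4 lists. It reversed the NF-kappaB list in M5 (-0.18) and M4 (-0.15), axon guidance in M5 (-0.14) and the mean of the lines (-0.10), NRF2 targets in the mean of the lines (0.0278), MHC in M4 (-0.0827) and p53 targets in M5 (0.0269). The block of 3 batches gave 63, 13, 49 for M4, 91 for M5, 7 for M4 against M1, 51 for M5 against M1 and 118 for M5 against M4, with 3 shared genes, and reversed axon guidance (-0.13) and p53 targets (0.0099) in M5. M5 as its first array alone gave 24 for the mean of the lines, 38 for M5, 34 for M5 against M1, 84 for M5 against M4 and 1 shared gene. It reversed in M5 the NF-kappaB list (-0.25), axon guidance (-0.15), p53 targets (0.0002) and the cell cycle (0.0058). Both changes together gave 90 for the mean of the lines, 43 for M1, 31 for M4, 14 for M4 against M1, 295 for M5 against M1, 343 for M5 against M4, 2 for luciferase, 7 shared genes and 1 list. They reversed the NF-kappaB list in M5 (-0.18) and M4 (-0.15), axon guidance (-0.14) and p53 targets (0.0269) in M5 and MHC in M4 (-0.0827). Without chromosome 3 the counts were 5 for the mean of the lines, 39 for M5, 32 for M5 against M1 and 68 for M5 against M4. With all genes in the adjustment, 142, 65 and 128 calls lay outside this chromosome in the same M5 comparisons. Its own genes therefore account for only part of the drop. The rest of the drop came from calls outside it that passed only with its genes included. The arrays and the group means fitted were the same, but limma's moderation of the spread was estimated anew without these genes. Many small p-values on chromosome 3 ease the Benjamini-Hochberg limit for all genes, but this effect was not tested apart from the moderation.

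Leaving out 1 array at a time, with a lone remaining array assumed to vary like the other groups, gave ranges of 0 to 292 for the mean of the lines, 0 to 14 for M1, 1 to 32 for M4, 54 to 3062 for M5, 2 to 7 for M4 against M1, 22 to 2366 for M5 against M1 and 69 to 2443 for M5 against M4. Luciferase stayed at 0 (118 to 313 unadjusted), the shared genes at 0, and the lists at 0 to 1. The highest M5 counts came without M5 replicate 1 and the lowest without M5 replicate 2 or 3 for M5, without M5 replicate 3 for M5 against M1 and without M4 replicate 2 for M5 against M4. The NF-kappaB median in M5 ranged from -0.0658 without M5 replicate 2, a reversal, to 0.1699 without M5 replicate 1.

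Other splits of the arrays tested whether chance can be excluded, each fitted as 2 groups of only the arrays compared, so that real counts differ from those above. It cannot for the mean of the lines, where the real split gave 1 gene, 11 of 100 splits gave as many and the highest other gave 1535. That split followed the batches, setting M4 replicates 2 and 3 and M5 replicates 2 and 3, all from batches 3 and 4, against the rest, and so points to a structure of the samples. With relabelling only within the 4 batches the real value was 10 and the highest other 2, and 1 of 30 splits reached it. This argues against chance but does not exclude it. The batches were formed after the data were seen, and arrays rather than lines were relabelled. Chance cannot be excluded for M1 (real 8, reached by 3 of 35 splits, highest other 336, which set the batch 1 arrays apart, where the block gave 28). Splits that ignore the batches argue against chance for M4 (real 38, highest other 7, 1 of 35) and for M5 (real 92, highest other 1, 1 of 35). They do not exclude it, since these real splits follow the batches in part. Relabellings within batches were too few, 9 for M1 (real 19, highest other 0), 3 for M4 (real 12, highest other 0) and 3 for M5 (real 30, highest other 1). For 3 arrays against 3 the splits were too few, with 4 and 216 for M4 against M1, where the highest split batch 3 from the rest and the block gave 14, 4 and 1 for M5 against M1, and 48 and 0 for M5 against M4. They were reached by 2, 1 and 1 of 10. For lists (highest other 7) and shared genes (highest other 0) the real count was 0, so that 100 of 100 splits had to give as many and the splits show nothing about chance.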

Other observations

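The camera tests of chromosome 5 were chosen only after the results were seen. Over the 270 of 507 chromosome 5 genes above the median signal, the median shift was 0.09 and 0.07 on the control arrays without luciferase. On those with it the median shift was -0.09 and -0.06. It was -0.16, -0.17 and -0.07 in M1, -0.22, -0.17 and -0.20 in M4 and 0.12, 0.01 and -0.01 in M5. The median for M4 against control was -0.17 (camera adjusted p = 0.00804 with an estimated correlation) and -0.24 with the 4 batches as a block (0.0145). For M1 it was -0.15 (0.0174, and 0.0513 with the block), and for luciferase -0.13 (0.024, and 0.103 with the block).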
